A study of Mus musculus with 8 samples.

How the data were processed

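Total RNA of isolated mouse pancreatic islets was hybridised by the authors to 8 Affymetrix expression arrays, 2 for each combination of genotype (wild type or hIAPP transgenic) and treatment (none or 4-phenylbutyrate, PBA). The deposited table holds 1 value per probe set and array, on the log2 scale, made by the authors with RMA. RMA subtracts background, sets all arrays to 1 distribution by quantile normalisation and summarises the probes of a set. The affy package is named for it, per the submitters' processing notes, without a version. The values are rounded to 1 decimal and were used as deposited, with no further transformation or filter on intensity. The number of arrays, 2 per group, limits the precision of a value, as do the rounding and, for dim genes, the background.

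The table has 45141 probe sets. The 104 control probe sets were left out of the tests and used to read array quality. Of the rest, 28898 name exactly 1 gene symbol, 551 name several and 15588 name none. Where several probe sets name 1 gene, as for 7180 genes, the set with the highest mean over the 8 arrays stood for the gene, which gave 17097 genes. Symbols were checked against RefSeq genes of the mouse assembly GRCm38.p6, which was also used for the order of neighbouring genes on a chromosome. Probe sets with several symbols or none entered only the fit of all 45037 non-control probe sets. Iapp, Ins1 and Mafa were not analysed here.

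The groups were compared with limma 3.58.1 in R 4.3.3. A single linear fit of all 8 arrays estimated 4 group means with 4 residual degrees of freedom, and the empirical Bayes step added 3.27 prior degrees of freedom around a prior SD of 0.132 (log2). The 8 comparisons were the transgene without PBA, PBA in hIAPP mice, PBA in wild-type mice, the transgene under PBA, PBA-treated hIAPP against untreated wild type, the interaction, and the transgene and PBA effects averaged over the other factor. All limma tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 17097 genes of a comparison, with a threshold of 0.05. Fold changes are on the log2 scale with the standard error (SE) of the fit, and group levels are means with their SD. Tables were handled with pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9. The labels do not say whether the 2 arrays of a group come from separate animals or from pools, so the p-values measure the spread between these samples.

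Sets of genes were tested on 30 lists of marker and pathway genes, 735 different genes in all. The lists cover beta-cell identity, beta-cell immaturity, other islet hormones, exocytosis, ER chaperones, the ATF4 and CHOP response, heat shock proteins, acinar, duct, macrophage, lymphocyte, stellate, endothelial, Schwann, fat and red blood cells, cytokines, interferon-stimulated genes, oxidative phosphorylation, hypoxia, antioxidant defence, autophagy, the proteasome, amyloid-associated proteins, sterol synthesis, fatty acid oxidation, the cell cycle, immediate early genes, apoptosis and sex-linked transcripts. Each list was tested with camera (two-sided, preset inter-gene correlation 0.01), and p-values were adjusted over the 30 lists of a comparison. Camera was repeated with an estimated correlation for each list, and fry was run beside it. Members past the threshold were also counted after adjustment over the list alone. The lists, the comparisons, the tests and the rule for the genes named in the text were chosen before the data were examined.

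The rule took, for each comparison of groups and for the interaction, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between groups. For the 2 averaged effects it took 5 and 5, with no overlap asked of all 4 against 4 arrays, and for the interaction no overlap was asked of either PBA arm. Up to 4 members of each list with the smallest p-values were added. Ins2, Gcg, Sst, Ppy, Pdx1, Slc2a2, Hspa5, Ddit3, Atf4, Xbp1, Trib3, Txnip, Cpa1 and Prss2 were named in any case. Predicted genes and small RNA genes were counted and not named, which left out 1 gene raised in untreated hIAPP islets, and 1 raised and 1 lowered by PBA in hIAPP islets. Genes named outside the rule are marked as chosen after their values were seen.

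Agreement between effects was measured by Pearson's correlation and covariance across genes, which are not independent replicates. Where 2 effects share arrays, the value that shared noise alone gives was simulated 100 times with no effect. The fit was tested on simulated data with 50 changed genes of each size. It recovered 2.0% of them at a log2 change of 0.5, 64.0% at 1, 92.0% at 2 and 100.0% at 3. It called 4 unchanged genes there, and 0 genes for PBA in wild-type mice when no change was simulated. Errors were drawn independently for each gene and array, so these counts do not cover variation that moves many genes together.

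The alternatives tried were a filter that kept the brighter 8526 genes, all probe sets in place of 1 per gene, cyclic loess renormalisation, the replicate number as a block, a fit of only the groups compared, array weights, a variance prior with trend and robust fitting, and each of the 8 arrays left out in turn. For lists, they were the estimated correlation and fry. In a comparison of 2 groups, leaving out either array of a group not compared gives the same gene fit, with unchanged folds. The 8 fits without 1 array are then not all distinct. Another 4 were chosen after seeing the data: the median level of the acinar list on each array as a covariate, uniform noise of at most 0.05 in place of the rounding, PBA-treated wild type 1 and PBA-treated hIAPP 1 both left out, and, for the agreement of the transgene and PBA effects in hIAPP islets, 1 untreated hIAPP array used for each effect.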

Results

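Gene expression was measured in pancreatic islets of 20-week-old mice on 8 arrays, 2 in each of 4 groups. Mice of an FVB/N background were wild type or carried the hIAPP transgene, which makes human islet amyloid polypeptide, an amyloid-forming peptide hormone, in beta cells. From the age of 8 weeks, mice of either genotype were left untreated or were given PBA, a chemical chaperone, at 1 g/kg/day for 12 weeks. Values of the 17097 genes tested are given on the log2 scale. Non-specific control probe sets had a median of 3.10, with a 95th percentile of 4.68. Pearson's correlation across genes was 0.993 to 0.994 for the 4 pairs of arrays within a group and 0.972 to 0.994 for the 24 pairs between groups. The first principal component held 54.1% of the variance and the second 13.4%. On the first, the untreated hIAPP arrays were at 45.0 and 42.7 and the other arrays at -23.2 to -5.5. The spiked-in hybridisation controls had a median of 6.60 on PBA-treated wild type 1 and of 9.30 to 9.70 on the other 7 arrays.

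Islets also carry RNA of the surrounding exocrine tissue. The median level of 34 acinar genes, which code for digestive enzymes, was 11.65 and 9.90 on the untreated wild-type arrays, 10.85 and 9.90 on the PBA-treated wild-type arrays, 10.30 and 11.75 on the untreated hIAPP arrays, and 7.65 and 9.45 on the PBA-treated hIAPP arrays. Ins2, an insulin gene, was at 14.00 to 14.05 in all 4 groups, at the top of the scale.

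**Figure D1:**
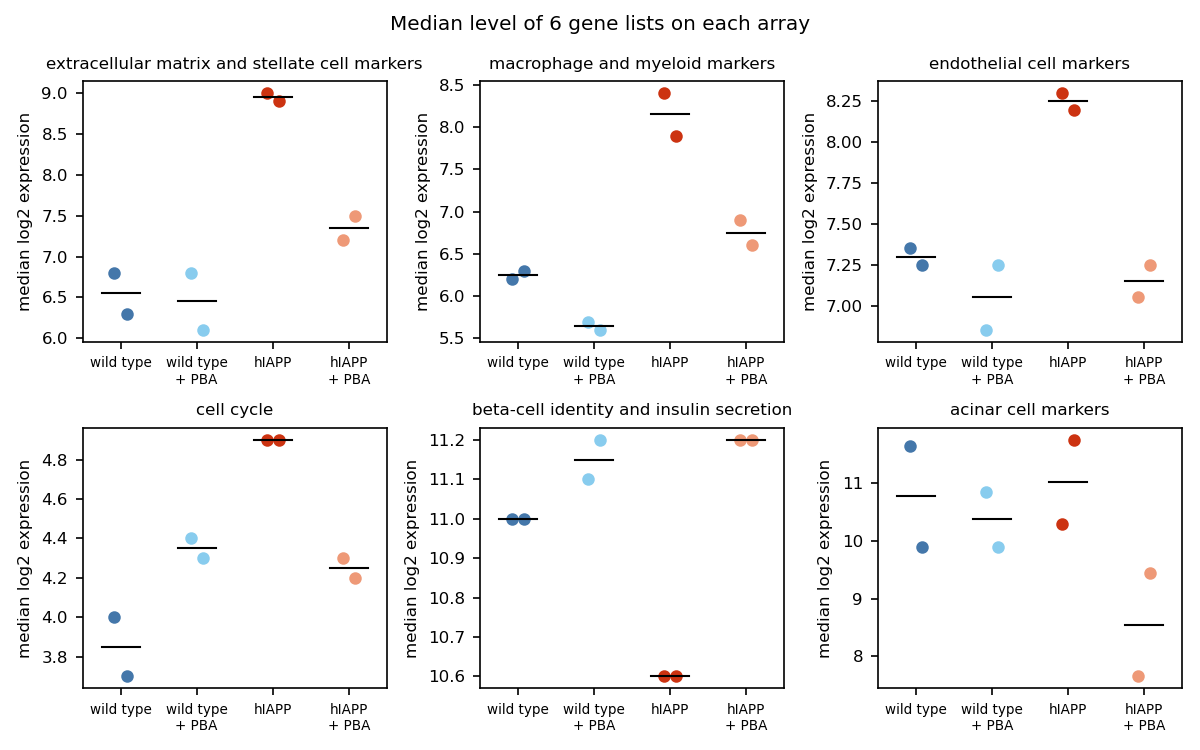
Median log2 expression (y axis) of the genes of 6 lists on each array (points), by group (x axis, 2 arrays each), with lines at the group means. The connective tissue list was at 8.90 and 9.0 on the untreated hIAPP arrays and at 6.10 to 7.50 on the other 6 arrays.

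As lists at the preset correlation, connective tissue, macrophage, endothelial and cell cycle genes were higher in untreated hIAPP than in untreated wild-type islets, and beta-cell genes were lower. With estimated correlations none of these lists passed, and 13 of 31 cell cycle genes and 6 of 25 beta-cell genes passed over all genes. This comparison asks which transcripts the transgene changed without treatment. Of 17097 genes, 1874 passed, 1329 of them higher and 545 lower in hIAPP islets. A change of at least 2-fold was seen for 715 of the raised and 49 of the lowered genes. Sema5a, a semaphorin gene, went from 5.0 ± 0.0 (SD, n = 2) to 9.80 ± 0.00 (n = 2), a log2 fold change of 4.80 (SE 0.12, adjusted p = 1.4e-05). The collagen gene Col8a1 (3.55, SE 0.23), the matricellular gene Smoc2 (3.55, SE 0.18), the matrix proteoglycan gene Lum (3.25, SE 0.35) and Crispld2 (3.30, SE 0.18) rose. So did the macrophage elastase gene Mmp12 (3.25, SE 0.17), the macrophage gene Gpnmb (3.45, SE 0.33), the arrestin-domain gene Arrdc4 (3.25, SE 0.13) and the immunoglobulin kappa segment Igkv15-103 (4.30, SE 0.76). For these 9 genes the adjusted p was at most 0.0120. Igkv15-103 passed in 4 of the 8 fits without 1 array, where its change was 2.95 to 5.65 (adjusted p up to 0.1273).

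The 10 named genes that fell in untreated hIAPP islets changed by -3.40 to -1.5, with adjusted p of at most 0.0237. Kcnf1, a potassium channel subunit gene, fell from 8.40 ± 0.14 to 5.0 ± 0.14 (SD, n = 2 each; -3.40, SE 0.17, adjusted p = 2.1e-04). Crybb3, a crystallin gene, changed by -2.55 (SE 0.15), Epb41l4a by -2.05 (SE 0.12) and the flavin monooxygenase gene Fmo1 by -2.0 (SE 0.16). The others were the endothelin gene Edn2 (-1.85), the carbonic anhydrase gene Car15 (-1.80), the phosphodiesterase gene Pde1c (-1.80), Pgap6 (-1.60), the splicing factor gene Rbm20 (-1.5) and Shisal2b (-1.5). Rbm20 passed in 1 of the 8 fits without 1 array (-1.95 to -1.05, adjusted p up to 0.2020) and Edn2 in 5 (-2.15 to -1.55, adjusted p up to 0.0790). In 3 of the 19 named genes, Igkv15-103, Smoc2 and Edn2, the lower group compared was below the 95th percentile of the non-specific controls, so the fold rests on a level near background.

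Extracellular matrix and stellate cell markers rose in 22 of 25 measured members, and in 23 adjusted over the list alone. Their median log2 fold change was 2.0 (camera adjusted p = 1.0e-24, adjusted p = 0.0570 with an estimated correlation). Among them were the collagen gene Col6a2 (2.70, SE 0.15), the periostin gene Postn (3.10, SE 0.22) and the smooth muscle actin gene Acta2 (2.25, SE 0.15). Of 31 macrophage and myeloid markers, 24 rose and 1 fell (28 and 1 adjusted over the list alone). Their median was 1.5 (camera adjusted p = 6.4e-21, adjusted p = 0.0570 with an estimated correlation), with Ms4a7 at 3.15 (SE 0.14), the lysosomal gene Cd68 at 2.60 (SE 0.15) and the lysozyme gene Lyz2 at 2.40 (SE 0.15). Endothelial markers rose in 15 of 22 members (19 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 7.1e-14, adjusted p = 0.0570 with an estimated correlation). The basement membrane collagen gene Col4a1 (1.35, SE 0.11) and Cd34 (1.20, SE 0.14) were among them. Acinar markers had a median of 0.23 (camera adjusted p = 0.8483) with 2 of 34 members lower, and their levels differed more between the 2 arrays of a group than between these 2 groups. Their median was 1.0 without wild type 1, 0.80 without hIAPP 1 and -0.48 without wild type 2, and the list passed in each of these 3 fits.

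Cell cycle genes rose in 13 of 31 members (20 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 1.3e-11, adjusted p = 0.0570 with an estimated correlation). Mki67 and Top2a, markers of dividing cells, each rose by 2.30. Their median level was 3.70 to 4.00 on the wild-type arrays, within the range of the non-specific controls, and 4.90 on both hIAPP arrays. Duct cell markers rose in 3 of 16 members (6 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 7.8e-04, adjusted p = 0.2699 with an estimated correlation). Bicc1 (1.60, SE 0.21), Ambp (1.25, SE 0.23) and the mucin gene Muc1 (1.80, SE 0.33) were the 3.

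Of 25 measured genes of beta-cell identity and insulin secretion, 6 fell and none rose (14 fell adjusted over the list alone). Their median was -0.35 (camera adjusted p = 4.5e-07, adjusted p = 0.1102 with an estimated correlation). The largest changes among those named were in the cation channel gene Trpm5 (-1.30, SE 0.14), the granule-tethering gene Sytl4 (-0.90, SE 0.11), the maturity marker Ucn3 (-0.85, SE 0.12) and the incretin receptor gene Gipr (-0.75, SE 0.12). Pdx1, a beta-cell transcription factor gene, and Slc2a2, the glucose transporter gene, each changed by -0.45 and did not pass (adjusted p = 0.0624 and adjusted p = 0.0823). Exocytosis genes fell in 5 of 18 members (6 adjusted over the list alone), among them Sytl4 of the previous list, Syt13 (-0.55) and Rab3a (-0.45). Their median was -0.30 (camera adjusted p = 1.3e-04, adjusted p = 0.1254 with an estimated correlation). Genes of beta-cell immaturity and genes normally kept silent in beta cells rose in 11 of 17 members and fell in 1 (12 and 1 adjusted over the list alone). Their median was 0.80 (camera adjusted p = 1.1e-07, adjusted p = 0.0570 with an estimated correlation). Aldh1a3 (2.35, SE 0.12), a marker of dedifferentiated beta cells, the neuronal repressor gene Rest (1.65, SE 0.11) and the lactate dehydrogenase gene Ldha (1.35, SE 0.15) rose, and Maob (-0.90, SE 0.10) fell. Pdgfra is on this list and on the connective tissue list, whose markers rose, so whole-islet RNA does not show which cells changed.

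Other islet hormone and endocrine genes had a median of 0.10 with 3 of 15 members raised, and the list did not pass (camera adjusted p = 0.0767), though it did without wild type 2 (median 0.20, adjusted p = 0.0325). The 3 were Fap (3.05, SE 0.29), which fibroblasts also express, Hhex (0.80) and Etv1 (0.75). The hormone genes Gcg (0.15, SE 0.11), Sst (-0.10, SE 0.13) and Ppy (-0.15, SE 0.10) did not pass (adjusted p = 0.4545, 0.6850 and 0.4079). ER chaperone genes had a median of -0.05, with 1 of 30 members raised and 1 lowered (camera adjusted p = 0.9418). Hspa5, the main ER chaperone gene, was at 0.15 (SE 0.12, adjusted p = 0.5157), and Ddit3, which codes for CHOP, at 0.25 (SE 0.12, adjusted p = 0.2476). Xbp1 (-0.05, SE 0.11), Atf4 (-0.15, SE 0.10) and Trib3 (0.30, SE 0.18) did not pass either. In the ATF4 and CHOP list, 5 of 23 members rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0332, adjusted p = 0.1461 with an estimated correlation). The list did not pass without hIAPP 2 (adjusted p = 0.0746), without either PBA-treated wild-type array (0.0517 each) or without both doubted arrays (0.0869). Txnip, a glucose-responsive gene of oxidative stress, rose by 1.80 (SE 0.13, adjusted p = 4.9e-04).

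In all, 18 of the 30 lists passed for the transgene, 16 up and 2 down, and 0 of them with estimated correlations. The count of 1874 genes was 484 when only the 4 arrays of these groups were fitted. It was 759 without wild type 1, 568 without wild type 2, 572 without hIAPP 1 and 811 without hIAPP 2.

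**Figure D2:**
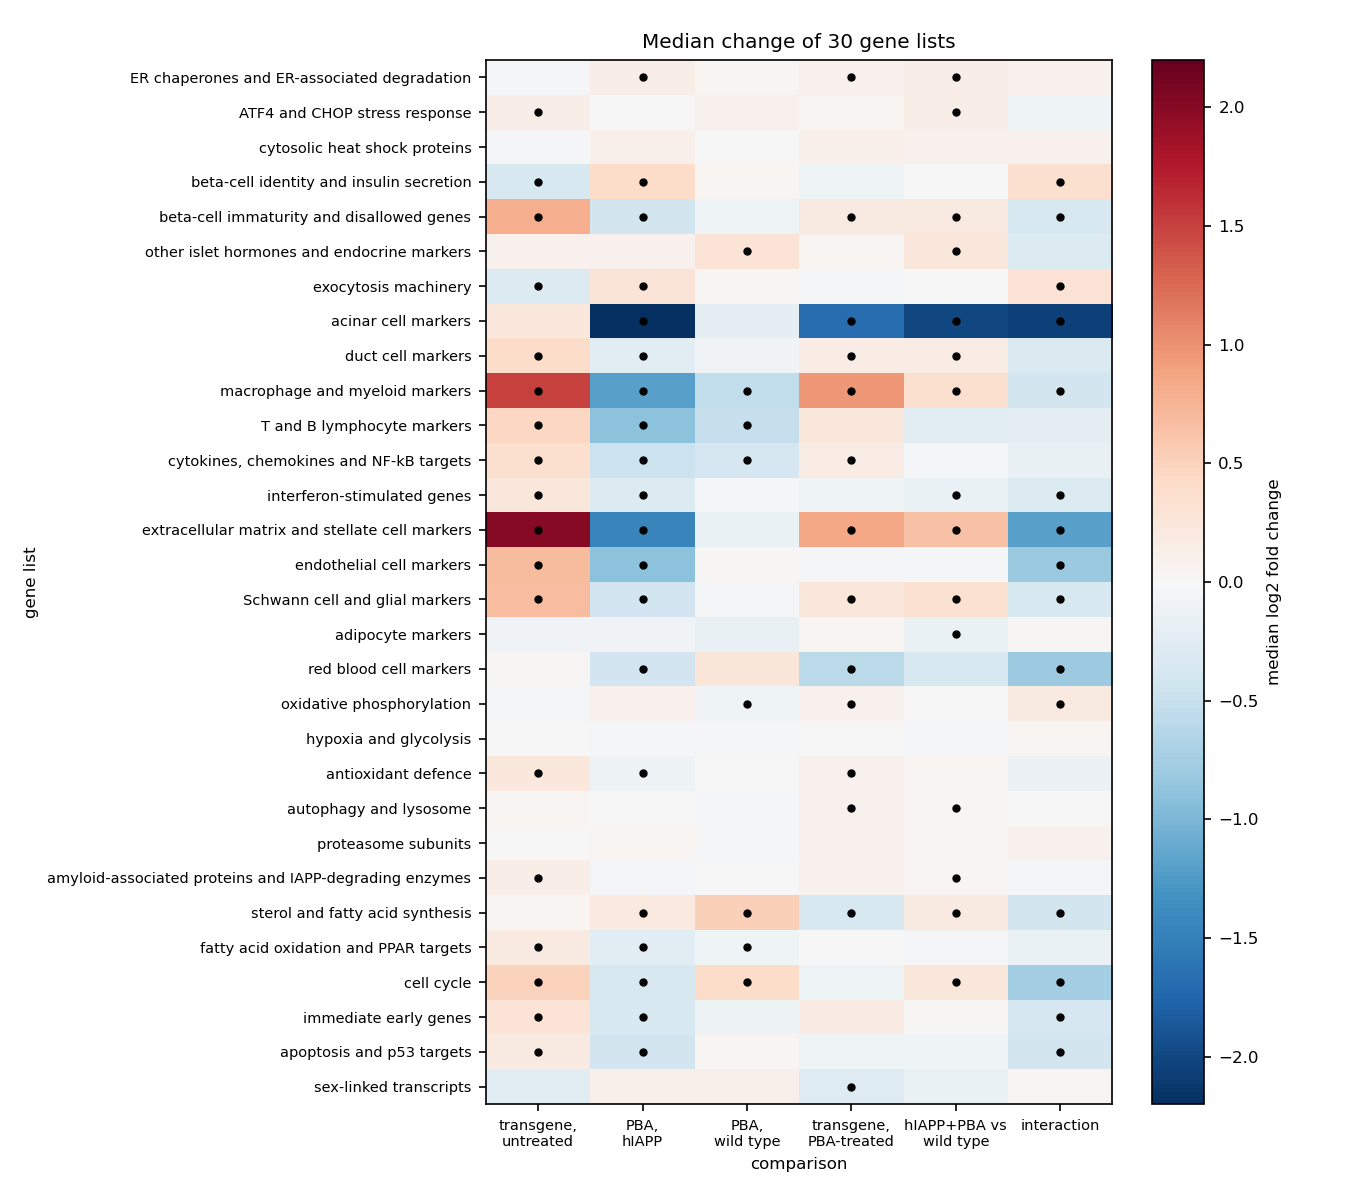
Median log2 fold change (colour) of 30 gene lists (y axis) in 6 comparisons (x axis), with a dot where camera with the preset correlation gave an adjusted p below 0.05. The lists for connective tissue (2.0) and macrophages (1.5) were raised by the transgene and lowered by PBA in hIAPP islets (-1.45 and -1.20) at the preset correlation. With estimated correlations neither list passed in either comparison.

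As lists at the preset correlation, connective tissue, macrophage, endothelial and cell cycle genes were lower with PBA in hIAPP islets, and beta-cell genes were higher. With estimated correlations the endothelial list alone passed, and 9 of 31 cell cycle genes and 7 of 25 beta-cell genes passed over all genes. The comparison of PBA-treated with untreated hIAPP islets asks what the drug changed in the transgenic mice. It gave 1384 genes past the threshold, 304 higher and 1080 lower under PBA. Of the lowered genes 597 changed at least 2-fold, and of the raised genes 18. Mmp12 fell from 9.0 ± 0.14 to 4.70 ± 0.00 (SD, n = 2 each; -4.30, SE 0.17, adjusted p = 1.8e-04). The chemokine genes Ccl9 (-3.20, SE 0.12) and Ccl21b (-3.90, SE 0.26), Gpnmb (-3.55, SE 0.33), Smoc2 (-3.45, SE 0.18) and the cytokine-like gene Cytl1 (-3.45, SE 0.23) fell. Igkv15-103 (-5.25, SE 0.76), Retnla (-3.75, SE 0.46), a marker of alternatively activated macrophages, and the carboxylesterase gene Ces1d (-3.40, SE 0.44) fell as well. The genes raised were the neuropeptide gene Npy (1.45, SE 0.18), Car15 (1.35, SE 0.14), the phosphodiesterase gene Pde10a (1.35, SE 0.21), Mirg, Plcxd2 and the cadherin gene Cdh8 (1.15 each), and Gpr137b, Ctnnal1 and Atat1 (1.10 each). In 7 of the 18 named genes the lower group was near background. With the acinar level of each array as a covariate, 7 of the 18 passed. Igkv15-103 was then at -3.47 (adjusted p = 0.1286) and Atat1 at 0.71 (adjusted p = 0.4564).

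Macrophage and myeloid markers fell in 24 of 31 members (27 adjusted over the list alone), with a median of -1.20 (camera adjusted p = 1.1e-22, adjusted p = 0.0780 with an estimated correlation). Cd74, of antigen presentation, changed by -1.30 (SE 0.10) and the mannose receptor gene Mrc1 by -2.30 (SE 0.21). Extracellular matrix and stellate cell markers fell in 21 of 25 members (24 adjusted over the list alone), with a median of -1.45 (camera adjusted p = 2.1e-21, adjusted p = 0.0780 with an estimated correlation). Acta2 (-1.85, SE 0.15), Fstl1 (-1.80, SE 0.16) and the desmin gene Des (-1.35, SE 0.12) were among them. Endothelial markers fell in 15 of 22 members (20 adjusted over the list alone), with a median of -0.90 (camera adjusted p = 1.1e-16, adjusted p = 0.0428 with an estimated correlation). They included the von Willebrand factor gene Vwf (-3.20, SE 0.26), the angiopoietin receptor gene Tek (-1.60, SE 0.16) and Pecam1 (-1.35, SE 0.15). Cell cycle genes fell in 9 of 31 members (15 fell and 1 rose adjusted over the list alone), with a median of -0.35 (camera adjusted p = 7.1e-07, adjusted p = 0.0949 with an estimated correlation). Mki67 changed by -1.5 (SE 0.18). The median level of the cell cycle list was 4.90 on both untreated hIAPP arrays and 4.30 and 4.20 with PBA. The PBA-treated levels lie below 4.68, the 95th percentile of the non-specific controls.

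Acinar markers were lower with PBA in the same islets. Their median change was -2.20, and 2 of 34 members, Cela3b (-2.20, SE 0.48) and Sycn (-3.15, SE 0.75), fell while 1 rose (26 and 1 adjusted over the list alone; camera adjusted p = 3.5e-07, adjusted p = 0.4282 with an estimated correlation). The acinar median was -1.5 without PBA-treated hIAPP 1 and -2.95 without PBA-treated hIAPP 2. The acinar gene that rose was Bhlha15 (1.05, SE 0.11), a transcription factor gene of secretory cells. Cpa1 (-2.15, SE 0.63) and Prss2 (-2.20, SE 0.67), enzyme genes, did not pass (adjusted p = 0.0904 and 0.0978). Duct cell markers fell in 3 of 16 members (5 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.0387, adjusted p = 0.4934 with an estimated correlation). The duct list passed in 1 of the 8 fits without 1 array, that without PBA-treated hIAPP 2 (range of the median -0.42 to -0.15). It did not pass with the acinar covariate or without both doubted arrays (adjusted p = 0.4172 and 0.3047). With the acinar level of each array as a covariate, the median of the connective tissue list was -1.23 and that of the macrophage list -1.31, and 116 genes passed in place of 1384.

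Beta-cell identity genes rose with PBA in 7 of 25 members (15 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.1e-08, adjusted p = 0.0949 with an estimated correlation). Gipr (0.75, SE 0.12), Sytl4 (0.70, SE 0.11), the proinsulin-processing gene Pcsk1 (0.60, SE 0.10) and the transcription factor gene Isl1 (0.60, SE 0.11) were among them. Pdx1 (0.40, SE 0.12, adjusted p = 0.1045) and Slc2a2 (0.45, SE 0.13, adjusted p = 0.0947) did not pass. Exocytosis genes rose in 3 of 18 members (6 adjusted over the list alone), Sytl4, Rab3a (0.55) and the calcium channel gene Cacna1d (0.45), with a median of 0.28 (camera adjusted p = 1.9e-05, adjusted p = 0.1033 with an estimated correlation). The immaturity list fell in 7 of 17 members and rose in 1 (9 and 2 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 1.5e-04, adjusted p = 0.0903 with an estimated correlation). Rest (-1.45, SE 0.11) and Ldha (-1.30, SE 0.15) fell, whereas Aldh1a3 was 9.75 without PBA and 9.55 with it. The connective tissue list, which shares Pdgfra with this one, also fell, so the cells behind these changes are not known. ER chaperone genes rose in 2 of 30 members (2 adjusted over the list alone), Syvn1 (0.85, SE 0.14) and Ero1a (0.55, SE 0.11), with a median of 0.15 (camera adjusted p = 4.0e-04, adjusted p = 0.1347 with an estimated correlation). Hspa5 (0.15, SE 0.12), Ddit3 (0.30, SE 0.12) and Xbp1 (-0.05, SE 0.11) did not pass. The ATF4 and CHOP list did not pass (camera adjusted p = 0.6677), although Txnip (-1.45, SE 0.13) and Ddit4 (-0.75, SE 0.11) fell and Atf4 (0.55, SE 0.10) rose.

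For PBA in hIAPP islets, 20 of the 30 lists passed, 4 up and 16 down, and 1 of them, the endothelial list, with estimated correlations. The count of 1384 genes was 14 when only the 4 arrays of these groups were fitted and 0 by limma without both doubted arrays, PBA-treated wild type 1 and PBA-treated hIAPP 1, where 3361 genes had an unadjusted p below 0.05. It was 166 without hIAPP 1, 332 without hIAPP 2, 266 without PBA-treated hIAPP 1, 432 without PBA-treated hIAPP 2 and 831 without either wild-type array. Of the 18 named genes, 6 passed in each of the 8 fits without 1 array: Mmp12, Ccl21b, Gpnmb, Cytl1, Smoc2 and Ccl9.

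Gene by gene, the PBA change in hIAPP islets ran against the transgene change. Of the 1329 genes raised in untreated hIAPP islets, 909 fell with PBA (84.0 by independence), and of the 545 lowered genes, 152 rose (9.7 by independence). The correlation of the 2 effects across genes was -0.82. They share the 2 untreated hIAPP arrays, and shared noise alone gave -0.50 in the simulation. The covariance was -0.164, against -0.014 from shared noise. In the comparison under PBA, which shares no array with the untreated one, the raised genes had a median change of 0.20 in place of 1.05, and 52 of them passed in the same direction. The lowered genes had a median of -0.15 in place of -0.60, and 6 of them passed in the same direction. To remove the noise of shared arrays, 1 untreated hIAPP array was used for the transgene effect and the other for the PBA effect, a division chosen after the data were seen. A difference common to both untreated hIAPP arrays, whatever its source, would still enter both effects. With or without the division, both effects were tested with the same variance estimate for each gene. The overlaps by independence in this paragraph therefore understate chance. The correlation was then -0.65 with hIAPP 1 for the transgene and -0.72 with hIAPP 2 for it. Of the 635 and 463 genes raised in these fits, 128 and 210 fell with PBA (5.8 and 8.1 by independence). Of the 176 and 109 lowered genes, 0 and 11 rose (0.1 and 0.2 by independence).

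**Figure D3:**
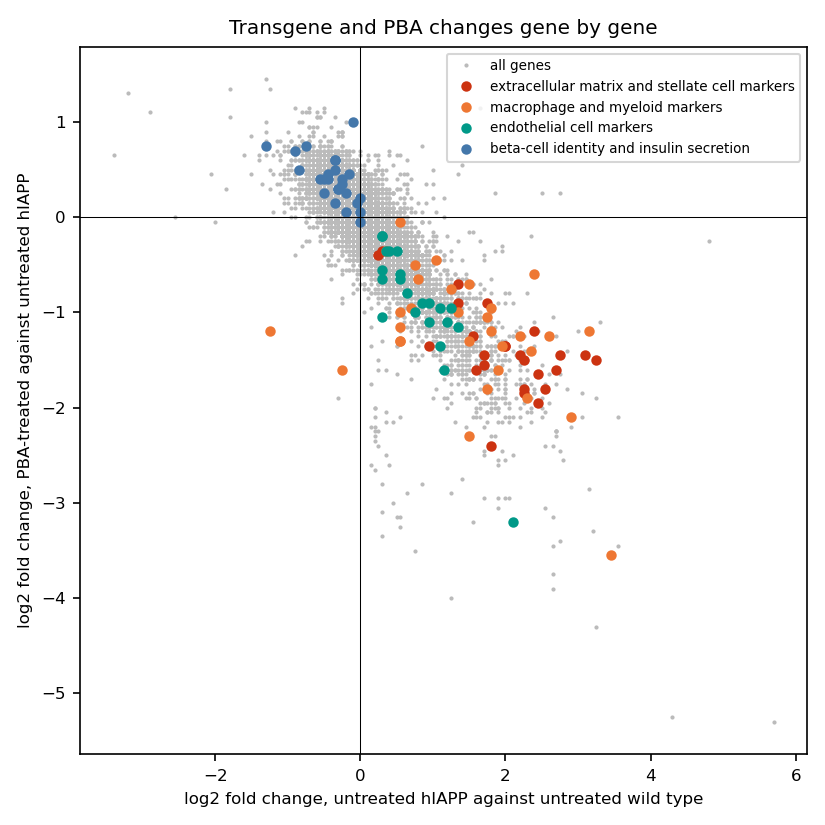
Log2 fold change of PBA-treated against untreated hIAPP islets (y axis) plotted over that of untreated hIAPP against untreated wild-type islets (x axis), 1 point per gene, with the members of 4 lists in colour. The correlation across the 17097 genes was -0.82, and the simulation with shared noise alone gave -0.50.

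In wild-type islets, PBA shifted sterol synthesis and cell cycle genes up and myeloid genes down as lists at the preset correlation. With an estimated correlation none of the 3 lists passed, and few of their members passed over all genes. This comparison asks what the drug changed without the transgene. It gave 50 genes past the threshold, 25 higher and 25 lower. The neutrophil and myeloid genes S100a8 (6.80 ± 0.28 to 3.85 ± 0.07, SD, n = 2 each; -2.95, SE 0.16, adjusted p = 0.0022) and S100a9 (-2.30, SE 0.26) fell. So did the galectin gene Lgals3 (-1.60), the leukocyte gene Lcp1 (-1.45), Ccl9 (-1.55), Mmp12 (-1.25), Crybb3 (-2.90, SE 0.15), Fmo1 (-1.70), the serpin gene Serpina3n (-1.65) and the ceruloplasmin gene Cp (-1.45). The cell cycle genes Ube2c (2.0, SE 0.18) and Ckap2 (1.20, SE 0.13), Npy (1.65, SE 0.18), Upk3a (1.60) and the Wnt inhibitor gene Sfrp5 (1.5) rose, as did Dusp4 and Dpp10 (1.30 each), Nptx1 and Etv5 (1.20 each) and Arrdc4 (1.15). The adjusted p of these 20 genes was at most 0.0423, and in 8 of them the lower group was near background.

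Sterol and fatty acid synthesis genes rose with PBA in wild-type islets in 6 of 22 members (16 rose and 1 fell adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.6e-12, adjusted p = 0.0959 with an estimated correlation). Cyp51 (0.95, SE 0.11) and Msmo1 (0.90, SE 0.12), enzyme genes of cholesterol synthesis, and Insig1 (0.95, SE 0.12), a sterol sensor gene, were among them. In hIAPP islets the same list had a median of 0.22, with 2 members raised and 1 lowered (5 and 1 adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.1033 with an estimated correlation). Macrophage markers fell in 2 of 31 members, S100a8 and S100a9 (20 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 5.1e-16, adjusted p = 0.1822 with an estimated correlation). Cell cycle genes rose in 1 of 31 members, Ube2c (10 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.5e-09, adjusted p = 0.1822 with an estimated correlation). The median level of the cell cycle list was 4.00 and 3.70 on the untreated and 4.40 and 4.30 on the PBA-treated wild-type arrays. All of these lie below 4.68, the 95th percentile of the non-specific controls. The other endocrine list had a median of 0.30 with no member past the threshold over all genes (4 adjusted over the list alone; camera adjusted p = 5.4e-04, adjusted p = 0.1822 with an estimated correlation). Acinar markers had a median of -0.20 (camera adjusted p = 0.1810), which was 0.47 without wild type 1 and 0.18 without PBA-treated wild type 2. It was -0.90 without wild type 2 and -0.70 without PBA-treated wild type 1, where the list passed, so its direction is not settled.

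Of the 25 genes lowered by PBA in wild-type islets, 13 also fell in hIAPP islets (1.6 by independence) and 2 rose (0.4 by independence). Of the 25 raised genes, 5 also rose (0.4 by independence) and 5 fell (1.6 by independence). Both effects were tested with the same variance estimate for each gene. Calls can therefore overlap beyond independence in either direction, and these values understate chance. The 2 PBA effects share no array, and their correlation across genes was 0.23. It was 0.10 without wild type 1 and 0.14 without PBA-treated wild type 2. In place of the 50 genes, limma gave 2 without either PBA-treated hIAPP array and 0 without any 1 of the other 6 arrays, where 1212 to 2881 genes had an unadjusted p below 0.05. With the replicate number as a block 5 genes passed, and 8 of the 30 lists passed, or 15 without PBA-treated wild type 1.

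Under PBA, the macrophage and connective tissue lists were higher in hIAPP than in wild-type islets at the preset correlation. With estimated correlations neither passed, and 10 of 31 and 1 of 25 members passed over all genes. The comparison asks which transgene effects remain in treated mice. It gave 72 genes, 55 higher and 17 lower. Sema5a was at 4.90 ± 0.00 in wild-type and 9.55 ± 0.21 in hIAPP islets (SD, n = 2 each; 4.65, SE 0.12, adjusted p = 1.7e-05). Snhg18, a noncoding RNA gene and its neighbour on chromosome 15 (GRCm38.p6), was higher by 2.60 (SE 0.10), Crispld2 by 2.80 (SE 0.18) and the phospholipase gene Pla2g7 by 2.65 (SE 0.13). Lyz2, the acid phosphatase gene Acp5 and the lipocalin gene Lcn2 (2.40 each), Cd68 (2.20), and Ms4a7 and Mpeg1 (2.15 each), mostly macrophage genes, were higher. Kcnf1 (-1.65), Npy (-1.5), Trpm5 (-1.25), Nptx1 and Dpp10 (-1.10 each), Fam184b and Ckap2 (-1.0 each), Ttc27 (-0.95) and the globin genes Hbb-b2 (-1.45) and Hba-a1 (-1.05) were lower.

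Macrophage markers were raised in 10 of 31 members in this comparison (20 rose and 2 fell adjusted over the list alone), with a median of 0.95 (camera adjusted p = 7.8e-17, adjusted p = 0.1696 with an estimated correlation). That median was 0.70 to 0.95 with 1 array left out and 0.60 without both doubted arrays. Of the connective tissue list 1 of 25 members passed, Col6a2 (16 adjusted over the list alone), and its median was 0.85 (camera adjusted p = 2.3e-15, adjusted p = 0.1696 with an estimated correlation). The endothelial (-0.05), beta-cell identity (-0.10) and cell cycle (-0.10) lists did not pass (camera adjusted p = 0.2625, 0.1527 and 0.0636). Aldh1a3 (2.0, SE 0.12) was the 1 member of the immaturity list past the threshold (5 adjusted over the list alone), and the list's median was 0.20 (camera adjusted p = 9.7e-04, adjusted p = 0.1696 with an estimated correlation). Without 1 array it was 0.10 to 0.40, and it did not pass without PBA-treated wild type 2 (adjusted p = 0.0581). The sterol list had a median of -0.35, with Stard4 lower (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.3e-06, adjusted p = 0.1696 with an estimated correlation). Acinar markers had a median of -1.67 with 0 of 34 members past the threshold (0 adjusted over the list alone; camera adjusted p = 1.3e-06, adjusted p = 0.4294 with an estimated correlation). That median was -0.87 without PBA-treated hIAPP 1, -2.37 without PBA-treated hIAPP 2 and -0.40 without both doubted arrays (adjusted p = 0.6131). The transgene effects with and without PBA, which share no array, had a correlation of 0.36 across genes.

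The 72 genes became 15 with the acinar covariate or with the replicate block, 38 with array weights, 1 without both doubted arrays and 0 by limma when only these 4 arrays were fitted, where 1902 genes had an unadjusted p below 0.05. They became 5 without 1 of the PBA-treated arrays of either genotype, 11 without 1 untreated wild-type array and 13 without 1 untreated hIAPP array, and Sema5a, Pla2g7, Snhg18 and Mpeg1 passed in each of these 8 fits. With the acinar covariate each of the 20 named genes kept its log2 value within 1.5 times (Kcnf1 -1.69, Acp5 2.37), while 9 of them passed. Of the lists, 14 passed, or 8 without PBA-treated wild type 2 and 9 without PBA-treated hIAPP 2.

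**Figure D4:**
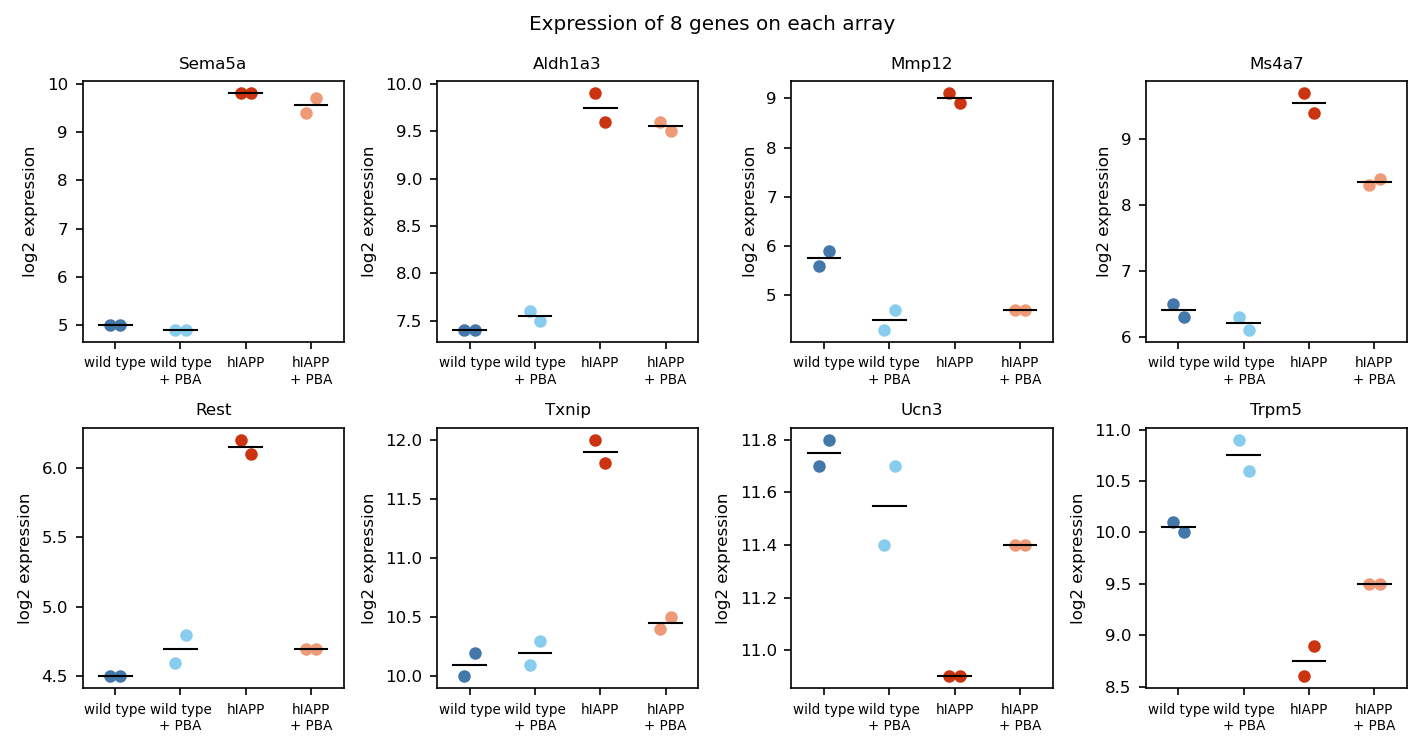
Log2 expression (y axis) of 8 genes on each array (points), by group (x axis, 2 arrays each), with lines at the group means. Sema5a and Aldh1a3 were high in hIAPP islets with PBA (9.55 each) and without it (9.80 and 9.75), whereas Mmp12 was at 9.0 without PBA and 4.70 with it.

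PBA-treated hIAPP islets differed from untreated wild-type islets in 63 genes, 43 higher and 20 lower. This comparison asks how far treated transgenic islets are from the untreated wild type. Higher were Sema5a (4.55, SE 0.12, adjusted p = 2.0e-05), Snhg18 (2.75, SE 0.10), the neuropeptide gene Grp (2.80, SE 0.35), Crispld2 (2.20), Aldh1a3 (2.15, SE 0.12), the lysine-degradation gene Aass (2.10), Ms4a7 and the neurofilament gene Nefl (1.95 each), and Tcf24 and Lyz2 (1.80 each). Lower were Kcnf1 (-2.75, SE 0.17), Crybb3 (-2.55), S100a8 (-2.45), Fmo1 (-2.05), S100a9 (-1.85), Ccl9 (-1.65), Epb41l4a (-1.60), the fatty acid transporter gene Cd36 (-1.35), and Apobec1 and Sox4 (-1.10 each). Connective tissue genes had a median of 0.65 with 2 of 25 members higher, Postn (1.65) and Col6a2 (1.10) (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.7e-10, adjusted p = 0.1516 with an estimated correlation). Macrophage markers had a median of 0.35, with 3 of 31 members higher and 3 lower (13 and 6 adjusted over the list alone; camera adjusted p = 0.0031, adjusted p = 0.3873 with an estimated correlation). The macrophage median was 0.15 without PBA-treated hIAPP 1 (adjusted p = 0.0570), 0.40 without wild type 2 (0.0803) and 0.55 without PBA-treated hIAPP 2. The list did not pass with the acinar covariate (adjusted p = 0.1590) or without both doubted arrays (0.1738). The beta-cell identity list had a median of 0.00 (camera adjusted p = 0.7960). ER chaperone genes had a median of 0.15 with 0 of 30 members past the threshold over all genes (4 adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.1516 with an estimated correlation). Acinar markers had a median of -2.0 with 0 members past the threshold (0 adjusted over the list alone; camera adjusted p = 1.8e-11, adjusted p = 0.3873 with an estimated correlation). The acinar median was -1.15 without PBA-treated hIAPP 1 and -1.28 without wild type 1.

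The 63 genes became 2 with the acinar covariate, 30 with the replicate block, 1 without both doubted arrays and 0 by limma when only these 4 arrays were fitted, where 2440 genes had an unadjusted p below 0.05. They became 2 without 1 array of the groups compared, 11 without 1 PBA-treated wild-type array and 16 without 1 untreated hIAPP array, and Sema5a and Snhg18 passed in each of these 8 fits. With the acinar covariate each of the 20 named genes kept its log2 value within 1.5 times, as for Kcnf1 (-2.75 to -2.80), Crispld2 (2.20 to 2.29), Aldh1a3 (2.15 to 2.03) and Fmo1 (-2.05 to -2.15), with adjusted p of 0.0626 to 0.0946 for these 4 genes.

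**Figure D5:**
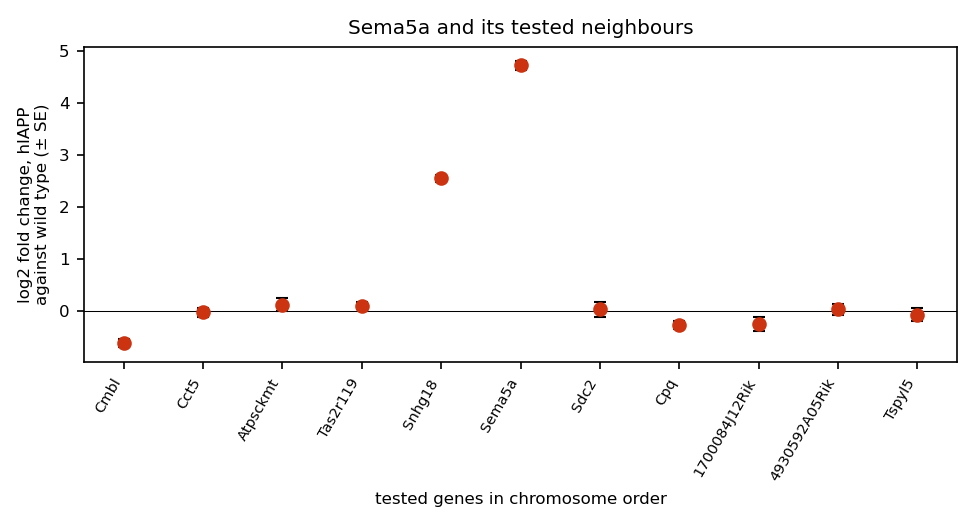
Log2 fold change, hIAPP against wild type averaged over treatment (y axis, points with SE), of Sema5a and the 5 nearest tested genes on either side in chromosome order (x axis, GRCm38.p6). Sema5a (4.72) and Snhg18 (2.55) were raised, and the other 9 genes lay between -0.62 and 0.12, with Cmbl (-0.62) and Cpq (-0.27) lower past the threshold.

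The PBA effect differed between the genotypes in 335 genes by the interaction, 289 of them lower and 46 higher in hIAPP than in wild-type islets. The cell cycle genes Top2a (-2.95, SE 0.29) and Ube2c (-2.90, SE 0.26) went from 3.30 and 3.55 to 4.65 and 5.55 with PBA in wild-type islets and from 5.60 and 5.55 to 4.00 and 4.65 in hIAPP islets. Cytl1 (-3.55, SE 0.32), Smoc2 (-3.50, SE 0.25), Ces1d (-3.50, SE 0.63), Arrdc4 and Mmp12 (-3.05 each), the prostaglandin receptor gene Ptger3 (-2.85), the mitotic kinase gene Pbk (-2.85) and the cholecystokinin gene Cck (-2.70) also had negative interactions. Positive ones were found for Crybb3 (2.90, SE 0.21), Car15 (2.35, SE 0.20), Kcnf1, S100a8 and Pde10a (1.75 each), Erich6 and Fmo1 (1.65 each), Shisal2b (1.60), Actn3 (1.55) and Gsdma (1.5). Txnip had an interaction of -1.55 (SE 0.18, adjusted p = 0.0168). In 12 of the 20 genes named by the rule the lowest of the 4 groups was near background.

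By list, the interaction was negative for connective tissue genes in 8 of 25 members (20 adjusted over the list alone), with a median of -1.20 (camera adjusted p = 8.0e-17, adjusted p = 0.1132 with an estimated correlation). It was negative for endothelial genes in 5 of 22 members (20 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 1.4e-15, adjusted p = 0.0479 with an estimated correlation). Cell cycle genes had a median of -0.75, with 7 of 31 members past the threshold (17 adjusted over the list alone; camera adjusted p = 5.7e-13, adjusted p = 0.1132 with an estimated correlation). The beta-cell identity list had a median of 0.35 with 0 of 25 members past the threshold (0 adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.1935 with an estimated correlation). Acinar markers had a median of -2.05 with no member past the threshold over all genes (3 higher adjusted over the list alone; camera adjusted p = 5.8e-04, adjusted p = 0.5521 with an estimated correlation). The acinar list did not pass without wild type 2 (-1.42), PBA-treated wild type 1 (-1.58), hIAPP 2 (-1.5) or PBA-treated hIAPP 1 (-1.37), nor without both doubted arrays (-0.85, adjusted p = 0.4597). With the acinar covariate each of the 20 named genes kept its log2 value within 1.5 times, as for Crybb3 (2.90 to 3.04), Smoc2 (-3.50 to -3.68), Mmp12 (-3.05 to -3.32) and Cytl1 (-3.55 to -3.34). The 335 genes became 6 with the covariate, which takes a degree of freedom, 534 with cyclic loess and 118 with the replicate block, and limma gave 0 without both doubted arrays, where 2555 genes had an unadjusted p below 0.05. Without 1 array limma gave 3 genes (PBA-treated hIAPP 2 left out), 1 (PBA-treated wild type 2 left out) and 0 (any of the other 6 left out), where 2252 to 2537 genes had an unadjusted p below 0.05.

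Averaged over treatment, the transgene changed 1499 genes, 1047 higher and 452 lower. The average joins unlike effects, since 1874 genes passed for the transgene without PBA and 72 under it. The genes named were chosen among those with all 4 hIAPP arrays on the same side of all 4 wild-type arrays. Sema5a (4.72, SE 0.08, adjusted p = 1.2e-06), Crispld2 (3.05, SE 0.13), Pla2g7 (2.83, SE 0.09), Ms4a7 (2.65, SE 0.10) and Acp5 (2.63, SE 0.15) rose. Kcnf1 (-2.52, SE 0.12), Edn2 (-1.65, SE 0.18), Epb41l4a (-1.48, SE 0.08), Trpm5 (-1.28, SE 0.10) and Ppil6 (-1.18, SE 0.15) fell. Connective tissue genes rose in 22 of 25 members (23 adjusted over the list alone; median 1.45, camera adjusted p = 2.1e-25, adjusted p = 0.0669 with an estimated correlation). The count was 906 with the acinar covariate and 1 without both doubted arrays. It was 752 and 558 without wild type 1 and 2, 689 without PBA-treated wild type 1, 512 and 761 without hIAPP 1 and 2, and 780 and 760 without PBA-treated hIAPP 1 and 2.

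Averaged over genotype, PBA changed 953 genes, 221 higher and 732 lower. The average joins unlike effects, since 1384 genes passed for PBA in hIAPP islets and 50 in wild-type islets. Msln (1.20, SE 0.20), the activity-dependent gene Npas4 (1.12, SE 0.14), Reep1 (0.95, SE 0.14), Cdh8 (0.90, SE 0.15) and the sterol reductase gene Tm7sf2 (0.85, SE 0.08) rose. Mmp12 (-2.77, SE 0.12, adjusted p = 3.4e-04), the chemokine genes Ccl21b (-2.58, SE 0.18), Ccl9 (-2.38, SE 0.08) and Ccl6 (-2.25, SE 0.17), and the protease inhibitor gene Slpi (-2.15, SE 0.31) fell. In 7 of these 10 genes the lowest of the 4 groups was near background. Macrophage markers fell in 25 of 31 members (26 adjusted over the list alone; median -0.88, camera adjusted p = 1.1e-26, adjusted p = 0.0607 with an estimated correlation). Sterol synthesis genes rose in 11 of 22 members (15 adjusted over the list alone; median 0.37, camera adjusted p = 9.2e-10, adjusted p = 0.0552 with an estimated correlation). The count was 75 with the acinar covariate, 586 with the replicate block and 0 by limma without both doubted arrays, where 3175 genes had an unadjusted p below 0.05. It was 180 and 357 without wild type 1 and 2, 87 and 96 without PBA-treated wild type 1 and 2, 106 and 224 without hIAPP 1 and 2, and 145 and 282 without PBA-treated hIAPP 1 and 2.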

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

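In this part, the tests of explanations for the 3 patterns weighed below were chosen only after the patterns were seen. The 2 patterns of cell markers and the pattern of Sema5a come from the comparison of hIAPP with wild-type islets. The other values are differences between groups, signals in probe sets without a gene name, or hybridisation controls far from those of other arrays.

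Connective tissue, macrophage and endothelial markers rose together in untreated hIAPP islets as lists at the preset correlation. With estimated correlations none of these lists passed. A smaller share of endocrine cells would raise every other cell type alike, yet the connective tissue list rose more than the endothelial list by a median of 1.30 (25 and 22 members, permutation p = 9.0e-05). The permutation moved genes between the lists, so its p-value treats genes as independent and does not measure the spread between samples. Acinar carry-over would lower the changes once the acinar level was a covariate, and the median over the 78 members was 1.35 with it as well as without it, with 59 in place of 61 past the threshold. The acinar levels of both groups overlapped (11.65 and 9.90 in wild type, 10.30 and 11.75 in hIAPP), so the covariate could change little. The list difference argues against an even rise of all other cells, and the overlapping acinar levels against acinar carry-over, as the whole account. Carry-over of other tissue was not tested. A rise in the number of macrophages and stellate cells, or in the activity of each, could give the pattern, and whole-islet RNA does not separate the 2.

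As a list at the preset correlation, beta-cell identity genes were lower in untreated hIAPP islets, and 6 of 25 members passed over all genes. With an estimated correlation the list did not pass. Dilution by RNA of other cells would lower all endocrine genes alike, but the beta-cell list changed by -0.65 relative to the other endocrine list (20 and 11 members below the top of the scale, permutation p = 5.3e-04). That p-value too treats genes as independent and does not measure the spread between samples. With the acinar level as a covariate the median stayed at -0.35, with 5 in place of 6 members past the threshold. As the acinar levels of both groups overlapped, the covariate could change little. That overlap itself makes acinar carry-over unlikely as the whole account. A loss of beta cells relative to other endocrine cells and a lower expression per beta cell both remain open. The other endocrine list includes genes that fibroblasts also express, which limits the first test.

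Sema5a and its neighbour Snhg18 were high on every hIAPP array, with and without PBA. A larger share of stromal or immune cells would make the 2 genes fall with PBA as their markers did. The change of Sema5a (-0.25) and Snhg18 (0.25) with PBA exceeded that of the connective tissue list by 1.45. The 2 genes were picked as high with and without PBA, so this largely restates the pattern. Such cells remain open where they stayed raised under PBA, with transgene medians of 0.95 (macrophage) and 0.85 (connective tissue). Of the 5 probe sets of the 2 genes 4 passed, which argues against cross-hybridisation of a single probe set. In 10000 shuffled gene orders, a nearest tested neighbour of Sema5a changed as much as Snhg18 in a share of 9.0e-04, but the pair was picked because Snhg18 changed, so this share decides nothing. Whether the change is local to this position on chromosome 15 stays open, as do the insertion site of the transgene and strain sequence beside it, and of the 9 other genes nearby 2 were lower, Cmbl (-0.62, adjusted p = 0.0035) and Cpq (-0.27, adjusted p = 0.0454), named after their values were seen.

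The PBA effect differed between hIAPP and wild-type islets in 335 genes with all 8 arrays. Leaving out 1 array gave 0 to 3 genes by limma, with 2252 to 2537 at an unadjusted p below 0.05 where it gave 0. Of the 15 lists that passed at the preset correlation, 1 passed with an estimated correlation, the endothelial list. With 1 array left out, the interaction medians of the Schwann cell and sterol synthesis lists were each -0.48 to -0.25. That of the acinar list was -2.77 to -1.37. The Schwann cell list did not pass with the acinar covariate (camera adjusted p = 0.0785). The medians of the interaction were 0.35 for the beta-cell identity list, -0.35 for beta-cell immaturity, 0.32 for exocytosis, -2.05 for acinar cells, -0.40 for macrophages, -0.30 for interferon-stimulated genes, -1.20 for connective tissue, -0.82 for endothelial cells, -0.35 for Schwann cells, -0.80 for red blood cells, 0.20 for oxidative phosphorylation, -0.40 for sterol synthesis, -0.75 for the cell cycle, -0.37 for immediate early genes and -0.40 for apoptosis. Among single genes it was 2.90 for Crybb3, 2.35 for Car15, 1.75 for Kcnf1, S100a8 and Pde10a, 1.65 for Erich6 and Fmo1, 1.60 for Shisal2b, 1.55 for Actn3 and 1.5 for Gsdma. It was -3.55 for Cytl1, -3.50 for Ces1d and Smoc2, -3.05 for Arrdc4 and Mmp12, -2.95 for Top2a, -2.90 for Ube2c, -2.85 for Ptger3 and Pbk, -2.70 for Cck and -1.55 for Txnip.

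Of the 15588 probe sets without a gene symbol, 601 passed for the transgene in untreated mice and 444 for PBA in hIAPP mice in the fit of all probe sets. The hybridisation controls of PBA-treated wild type 1 lay 2.70 below the lowest other array. Its correlation with its replicate, 0.9933, was by a small margin the lowest of the 4 replicate pairs (0.9938 to 0.9942 for the others). That pair had the largest SD of replicate differences (0.281, against 0.258 to 0.267). It also had the fewest genes differing by over 1 log2 (40, against 64 to 83).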

How the results depend on the processing

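In this part, the acinar covariate, the noise in place of rounding, the division of the untreated hIAPP arrays and the fit without both doubted arrays (PBA-treated wild type 1 and PBA-treated hIAPP 1) were chosen after seeing the data. PBA-treated wild type 1 had low hybridisation controls (6.60). PBA-treated hIAPP 1 had ordinary ones (9.60), and the lowest acinar (7.65) and duct (5.10) list levels of all arrays. The rule named 81 different genes in 137 pairs of gene and comparison, and 0 of these pairs changed direction in the settings where their folds were recomputed. These exclude the fit of only the groups compared and the prior with trend, and 94 of the pairs were in the fit without dim genes. Counts below follow the order of the comparisons in the methods. Their values with all arrays were 1874, 1384, 50, 72, 63, 335, 1499 and 953 genes, and 18, 20, 8, 14, 15, 15, 22 and 18 lists.

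Fitting only the groups compared gave 484 genes for the transgene in untreated mice, 14 for PBA in hIAPP mice, and 0 for PBA in wild-type mice, for the transgene under PBA and for PBA-treated hIAPP against untreated wild type. This fit has 2 residual degrees of freedom in place of 4, which shows the cause in part. With all probe sets, 2820 passed for the transgene in untreated mice, where 45037 probe sets replaced 17097 genes. A prior with trend and robust fitting gave 2295 (PBA in hIAPP mice), 299 (PBA in wild-type mice), 348 (transgene under PBA), 367 (PBA-treated hIAPP against wild type), 1059 (interaction) and 1656 (averaged PBA effect), and the cause was not tested. The replicate block gave 5 (PBA in wild-type mice), 15 (transgene under PBA), 30 (PBA-treated hIAPP against wild type), 118 (interaction) and 586 (averaged PBA effect). Replicate differences correlated at -0.14 to 0.10 between groups, which shows no strong shared replicate effect. It cannot show whether the replicate numbers pair the arrays, which the labels do not state. The block also uses up 1 residual degree of freedom. Dim genes left out gave 87 for PBA in wild-type mice, where 8526 genes were tested. Cyclic loess gave 86 for PBA in wild-type mice and 534 for the interaction, and array weights 38 for the transgene under PBA, and the cause was not tested.

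The acinar covariate gave 116 genes (PBA in hIAPP mice), 15 (transgene under PBA), 2 (PBA-treated hIAPP against wild type), 6 (interaction), 906 (averaged transgene effect) and 75 (averaged PBA effect). It takes 1 of 4 degrees of freedom, and the acinar level moved with PBA in hIAPP mice, which widens the error of that effect. For PBA in hIAPP mice the folds changed less than the calls: the macrophage median went from -1.20 to -1.31 (adjusted p = 2.8e-24), connective tissue from -1.45 to -1.23 (adjusted p = 1.4e-16), endothelial from -0.90 to -0.82 (adjusted p = 2.3e-14), and Mmp12 from -4.30 to -4.62 (adjusted p = 0.0056). The lymphocyte median moved more, from -0.90 to -0.52 (camera adjusted p = 0.0115). Noise in place of rounding gave 82 for PBA in wild-type mice and 96 for PBA-treated hIAPP against wild type. It raised the prior degrees of freedom from 3.27 to 4.91, which shows the cause in part. Without both doubted arrays the counts were 484 (transgene in untreated mice), 0 (PBA in hIAPP mice), 0 (PBA in wild-type mice), 1 (transgene under PBA), 1 (PBA-treated hIAPP against wild type), 0 (interaction), 1 (averaged transgene effect) and 0 (averaged PBA effect) by limma. There 2 residual degrees of freedom were left, with 0.85 prior degrees of freedom in place of 3.27. Where it gave 0, an unadjusted p below 0.05 was found for 3361, 1649, 2555 and 3175 genes in the same order. For the 3 comparisons with 0 genes when only their groups were fitted, it was found for 1802, 1902 and 2440 genes.

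Leaving out each array in turn, where the lone array is assumed to vary like the other groups, gave 568 to 1579 genes for the transgene in untreated mice, 166 to 968 for PBA in hIAPP mice, 0 to 2 for PBA in wild-type mice, 5 to 13 for the transgene under PBA, 2 to 16 for PBA-treated hIAPP against wild type, 0 to 3 for the interaction, 512 to 1033 for the averaged transgene effect and 87 to 357 for the averaged PBA effect. At 0 genes by limma, an unadjusted p below 0.05 was found for 1212 to 2881 genes. The prior degrees of freedom fell from 3.27 to 1.51 to 2.15 and the residual ones from 4 to 3. The fold changes correlated with those of all arrays at 0.85 to 1.00. Lists past the threshold numbered 17 to 19, 18 to 20, 6 to 15, 8 to 14, 11 to 16, 13 to 17, 20 to 22 and 17 to 19.

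With an estimated correlation, 0, 1, 0, 0, 0, 1, 0 and 0 lists passed. By construction, camera then takes its p-value from 4 degrees of freedom in place of nearly the number of genes, and widens the variance only for lists whose correlation exceeds the preset 0.01. Some lists that lost the call had a lower one, such as interferon-stimulated and Schwann cell genes for the transgene in untreated mice. By fry, 4 lists passed for PBA in wild-type mice and 7 for the transgene under PBA, and without both doubted arrays 8 for the transgene under PBA, and the cause was not tested.

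The correlation of the transgene effects with and without PBA (0.36) was 0.42 without dim genes, 0.31 with all probe sets and 0.27 to 0.38 with an array left out. That of the PBA effects (0.23) was 0.10 to 0.29. That of the transgene and PBA effects (-0.82) was -0.79 with all probe sets, -0.78 with the acinar covariate and -0.84 to -0.75 with an array left out. With the untreated hIAPP arrays divided between the 2 effects it was -0.65 (hIAPP 1 for the transgene) and -0.72 (hIAPP 2 for the transgene), since this removes the noise of shared arrays and leaves 1 array for each effect. The division does not remove a difference common to both untreated hIAPP arrays.

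Some list results reversed. The acinar list was at -0.48 for the transgene in untreated mice without wild type replicate 2, in place of 0.23 (range -0.48 to 1.0). With the acinar covariate, which removes it by construction, its median shrank without changing sign, to -0.10 for PBA in hIAPP mice in place of -2.20 and to -0.03 for the averaged PBA effect in place of -1.26, while the direction of its camera test changed. Without PBA-treated hIAPP replicate 2, the duct list was at -0.07 for the transgene under PBA (range -0.07 to 0.38) and at -0.05 for PBA-treated hIAPP against wild type (range -0.05 to 0.35), in place of 0.17 each. This array had the higher duct level of the pair, 6.90 against 5.10.

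Signal over background limits the dim genes: non-specific controls reached 4.68 at the 95th percentile, and the lowest of the 4 groups lay below it in 12 of the 20 genes named for the interaction, 7 of the 10 for the averaged PBA effect and 2 of the 10 for the averaged transgene effect.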

Other observations

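In this part, the split tests were set in advance, and no test was chosen after a result was seen. Further gene lists were changed in untreated hIAPP islets. Immediate early genes rose in 10 of 26 members (12 adjusted over the list alone; median 0.30, camera adjusted p = 3.3e-07, adjusted p = 0.0651 with an estimated correlation), with the nuclear receptor gene Nr4a3 at 2.35. Apoptosis and p53 target genes rose in 9 of 25 (11 alone; median 0.20, camera adjusted p = 1.6e-04, adjusted p = 0.0668 with an estimated correlation), among them the ER-located caspase gene Casp12 (1.55) and the cell cycle inhibitor gene Cdkn1a (0.95). Cytokines and NF-kB targets rose in 8 of 28 (10 rose and 1 fell alone; median 0.35, camera adjusted p = 1.3e-04, adjusted p = 0.2231 with an estimated correlation), with the adhesion gene Icam1 at 1.80. Interferon-stimulated genes rose in 3 of 22 (5 alone; median 0.25, camera adjusted p = 1.3e-04, adjusted p = 0.0570 with an estimated correlation), and the antioxidant list in 7 of 24 (8 alone; median 0.23, camera adjusted p = 0.0046, adjusted p = 0.0835 with an estimated correlation), with the catalase gene Cat at 1.60. Amyloid-associated genes rose in 6 of 21 (8 alone; median 0.15, camera adjusted p = 4.9e-04, adjusted p = 0.1260 with an estimated correlation), among them the apolipoprotein gene Apoe (1.70) and the cathepsin gene Ctsd (1.20). Schwann cell genes rose in 5 of 12 (7 alone; median 0.68, camera adjusted p = 1.6e-04, adjusted p = 0.0570 with an estimated correlation), with the myelin gene Pmp22 at 1.65. Lymphocyte genes rose in 2 of 17 (2 alone; median 0.45, camera adjusted p = 0.0080, adjusted p = 0.4347 with an estimated correlation), Cd3d and Cxcr5 (1.15 each). The median level of this list was 4.60 and 3.70 on the untreated wild-type arrays and 4.70 and 4.80 on the untreated hIAPP arrays. With PBA it was 3.60 on both wild-type arrays and 4.00 and 3.80 on the hIAPP arrays. These levels are near or below 4.68, the 95th percentile of the non-specific controls. The lymphocyte median was 0.95 without wild type 1 and 0.15 without wild type 2, where the list did not pass (adjusted p = 0.3676). Fatty acid oxidation genes rose in 6 of 23 and fell in 1 (9 and 1 alone; median 0.20, camera adjusted p = 0.0104, adjusted p = 0.1102 with an estimated correlation), and the list did not pass without hIAPP 1 (median 0.15, adjusted p = 0.0509).

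The lists for oxidative phosphorylation (camera adjusted p = 0.1620), the proteasome (0.9418), autophagy (0.0588), heat shock proteins (0.8673), hypoxia (0.8223), sterol synthesis (0.9658), fat cells (0.8483), red blood cells (0.7360) and sex-linked transcripts (0.0767) did not pass for the transgene in untreated mice.

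With PBA in hIAPP islets, cytokines and NF-kB targets fell in 9 of 28 (13 adjusted over the list alone; median -0.48, camera adjusted p = 9.0e-07, adjusted p = 0.1347 with an estimated correlation), with Icam1 at -2.30. Interferon-stimulated genes fell in 6 of 22 (10 alone; median -0.30, camera adjusted p = 6.5e-07, adjusted p = 0.0656 with an estimated correlation), with the GTPase gene Iigp1 at -2.10. Immediate early genes fell in 8 of 26 and rose in 1 (13 and 1 alone; median -0.33, camera adjusted p = 1.2e-06, adjusted p = 0.0903 with an estimated correlation), and apoptosis genes fell in 7 of 25 (12 fell and 1 rose alone; median -0.40, camera adjusted p = 1.6e-05, adjusted p = 0.0780 with an estimated correlation), with Casp12 at -1.70. Lymphocyte genes fell in 3 of 17 (4 alone; median -0.90, camera adjusted p = 7.1e-05, adjusted p = 0.2818 with an estimated correlation), and fatty acid oxidation genes in 5 of 23 (8 fell and 1 rose alone; median -0.25, camera adjusted p = 0.0023, adjusted p = 0.0949 with an estimated correlation), with Cd36 at -2.75. PBA lowered some of these lists in wild-type islets too at the preset correlation. Their medians were -0.37 for cytokines (camera adjusted p = 6.7e-07), -0.50 for lymphocytes (0.0011) and -0.10 for fatty acid oxidation (0.0318). Interactions of these lists did not pass (camera adjusted p = 0.0984, 0.1766 and 0.0846). In wild-type islets the interferon, immediate early and apoptosis lists did not pass (camera adjusted p = 0.4415, 0.2764 and 0.9831).

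The 8 arrays can be split into 4 and 4 in 35 ways, and each split was compared by limma as 2 groups. The split by genotype gave 62 genes and the highest other split 0, so 1 of 35 splits reached the count. This share, 0.029, is the smallest that 35 splits allow. Every other split mixes the genotypes, which leaves their difference in the residual. The share covers the 62 genes of this fit and not the 1499 genes of the fit with 4 group means. It does not test for a difference in preparation between the genotypes. The split by PBA gave 0 genes by limma, with 1777 at an unadjusted p below 0.05, so all 35 of 35 splits reach its count by construction, and the count says nothing on chance for the averaged PBA effect. The highest other split was the genotype split with 62, a structure of the samples. By unadjusted counts 2 other splits exceeded the PBA split, the genotype split (2670) and 1 more (1836). The 2-group fit leaves the genotype difference in the residual. The fit with 4 group means gave 953 genes for it.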
